A study of Cereibacter sphaeroides 2.4.1 with 4 samples.

How the data were processed

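The series holds 4 libraries of RNA from co-immunoprecipitation with anti-FLAG beads in Rhodobacter sphaeroides 2.4.1, with 1 library per group. Values of the FLAG_6037 and control_6037 libraries were analysed. The FLAG_0557 and control_0557 libraries were not analysed here. Groups were taken from the plasmid named in the labels.

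Reads were trimmed with Trimmomatic, and DESeq2 1.22.1 and DESeq were used, per the submitters' processing notes. The aligner, the counting tool and the genome build are not given in the sources used here. The deposited read counts are expected counts, called raw countings per the file headers. They carry fractions of a read, with 91.6% of values not whole in the FLAG library and 82.3% in the control, and they count sense reads. The table holds 4280 coding sequences, 54 tRNAs, 9 rRNAs, 51 rows of non-coding RNA and 16 rows of small RNA. The deposited mean signal, log2 fold change and its standard error come from the authors' fit, per the file headers. The deposited score is the log2 fold change over its standard error. All 80 features with 0 reads in both libraries have a deposited mean above 0, so other libraries entered that fit. The deposited log2 fold changes equal the log2 ratio of the rounded counts less 0.86 to within 0.01 in 99.7% of the 3456 features with at least 5 reads in both libraries. Gene names are those of the deposited table, because none of its locus tags matched the reference annotation at hand.

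Expected counts were rounded to whole reads, and a value midway between whole numbers went to the even one. Such values were first rounded upward. The rule was changed after results under it had been seen, because the authors' log2 fold changes followed from the counts in 94.4% of features under the first rule and in 99.7% under the second. The first rule gave 102 enriched features in place of 101, and the same number of depleted ones, 67.

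Counts were scaled with the median-of-ratios size factors of DESeq2 1.42.0, whose ratio of FLAG to control was 1.88. The ratio of scaled counts was given an exact conditional binomial 95% interval. Intervals of ratios and of read shares (Clopper-Pearson) cover counting error only, and PCR copies are not independent molecules. Intervals of medians come from the ranked log2 ratios of the members. They take members as independent, though adjacent genes were correlated and some tRNA copies had identical counts. With 1 library per group there is no estimate of biological spread and no test across replicates was run. A feature with at least 20 reads over both libraries was called enriched where the interval lay above 2 and depleted where it lay below 0.5.

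On data simulated for the FLAG_6037 and control_6037 comparison with counting noise alone, over 3279 features, the procedure called 80.0% of 4-fold and 98.0% of 8-fold increases. It called 87.5% of decreases to 0.25 and 100% of decreases to 0.125, and 1 of 3081 unchanged features.

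For each gene list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, drawn from features other than rRNA and tRNA. These percentiles describe the 2 libraries. They take genes as independent, while adjacent coding sequences on the same strand less than 50 nt apart had correlated log2 ratios (Pearson r 0.71, Spearman rho 0.52, across 1077 pairs of genes, which are not replicates). The 24 gene lists, the scaling, the limits and the rule for named features were fixed before the data were examined. The list of housekeeping RNAs matched no feature, and the DUF1127 list matched RSP_6037 alone. After the data were examined, product names were matched without regard to case, because the catalase gene would otherwise have been missed.

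Named features are the 15 with the highest lower bound and the 15 with the lowest upper bound outside rRNA, RSP_6037 and RSP_0557, known small RNAs and DUF1127 matches, the highest and lowest member of each list, and the 5 most-read features of each library. Features named outside this rule are marked as such. Alternatives were total count, TMM (edgeR 4.0.16), total count without rRNA and tRNA and upper-quartile scaling, read minimums of 50 and 1, limits of 4-fold and 1.5-fold, an assumed coefficient of variation of 0.2 or 0.4, and shares outside rRNA or tRNA. Added after the data were examined were the size factor ratio implied by the authors' fold changes, identical counts taken once, rRNA and tRNA left out, matching with case, upward rounding, and 9 gene lists taken again by annotated product, without members annotated with another function and with sigma factor, anti-sigma factor, Calvin cycle, cytochrome and iron genes that the symbols or product words had missed. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.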

Results

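RNA that co-purified with the small DUF1127-domain protein RSP_6037 was sequenced from Rhodobacter (Cereibacter) sphaeroides 2.4.1, a bacterium that can grow by respiration or by photosynthesis. The FLAG library came from cells with a plasmid copy of RSP_6037 that carried a FLAG tag, and the control library came from cells with the same plasmid without the tag. Both cultures grew in the dark at 25 µM dissolved oxygen and 32 °C and were harvested in exponential phase. Lysates were then incubated for 2 h with anti-FLAG beads. A second pair of libraries, for the protein RSP_0557, belongs to the series and was not analysed here. Each group held 1 library, so no difference has a replicate check. All ratios compare these 2 libraries and not the conditions.

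The FLAG library held 33732827 counted reads and the control library held 14221662, over 4410 annotated features. The median feature had 42 reads in the FLAG library and 23 in the control. Ratios are FLAG over control after scaling by the median of ratios, and their 95% intervals cover counting error only. A feature is called enriched where its interval lies above 2 and depleted where it lies below 0.5, among the 3275 features with at least 20 reads over both libraries. Positions are those of the authors' table, whose genome build is not given in the sources used here.

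The comparison asks which RNAs are retrieved with tagged RSP_6037. Its own gene, RSP_6037 on chromosome 1 at 692457 to 692672, had 1701 reads in the FLAG library and 628 in the control, a ratio of 1.44 (interval 1.32 to 1.59) that is neither enriched nor depleted. Both strains carry a plasmid copy of this gene, so its level does not check the labels. The 3 small RNAs encoded directly downstream on the same strand had higher ratios. RSs0680a, known as CcsR1, lies at 692372 to 692455 and was enriched at 3.17 (interval 2.96 to 3.41, 5388 against 906 reads). RSs0680b had a ratio of 2.13 (interval 1.78 to 2.58) and RSs0680c a ratio of 2.28 (interval 1.88 to 2.78). RSP_0557, the other protein studied in this series, had a ratio of 0.98 (interval 0.91 to 1.06), which total-count scaling moved to 0.776 (interval 0.719 to 0.837).

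**Figure D1:**
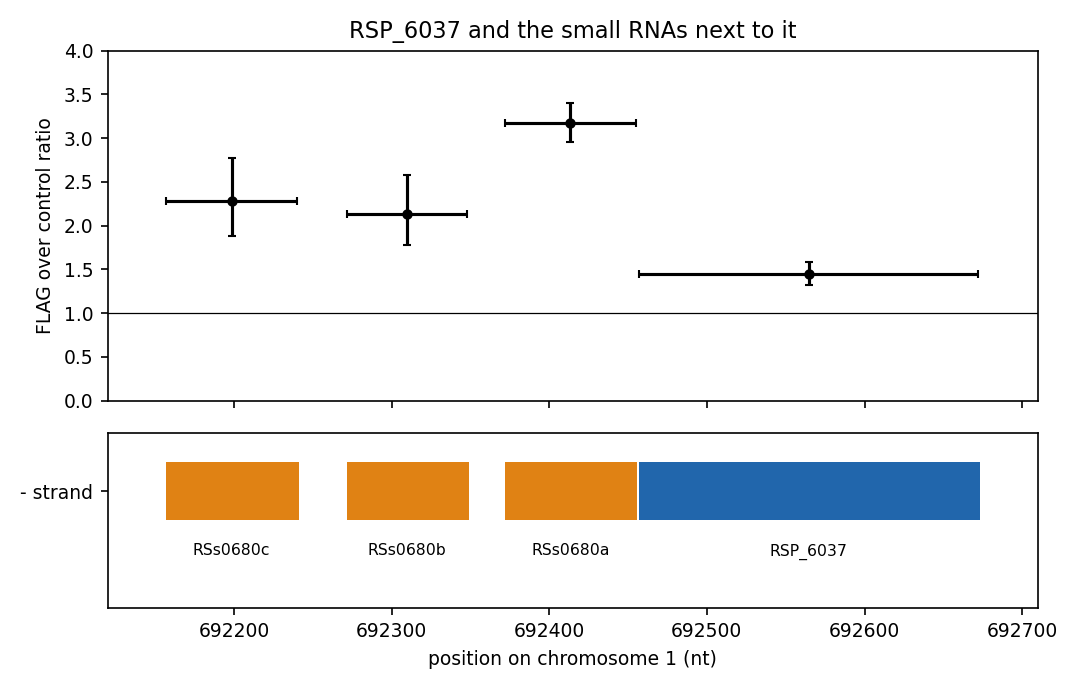
FLAG over control ratio (vertical axis, linear, vertical bars are 95% counting intervals) of RSP_6037 and 3 small RNAs against position on chromosome 1 (horizontal axis in nt, horizontal bars span each feature), with the features drawn to scale (blue, coding sequence; orange, small RNA). RSs0680a at 3.17 sits above RSP_6037 at 1.44.

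Over all features, 101 were enriched and 67 were depleted. The enriched features comprised 77 coding sequences, 20 tRNAs and 4 small RNAs, and the depleted ones comprised 66 coding sequences and 1 small RNA. The largest difference was in catA (RSP_2779, chromosome 1, 1426912 to 1428378), which encodes catalase, an enzyme that breaks down hydrogen peroxide. It had 7856 reads in the FLAG library and 35 in the control, a ratio of 120 (interval 86.0 to 172). All 4 genes of the Sit manganese and iron transporter were enriched, from sitA at 42.9 (interval 29.4 to 65.3) and sitD at 32.2 (interval 20.8 to 53.0) to sitC at 19.1 and sitB at 18.7. With total-count scaling the split turned to 63 enriched and 150 depleted features.

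Adjacent genes on chromosome 1, between 538988 and 542900, were enriched together. RSP_1943, a protein of unknown function, had a ratio of 34.0 (interval 19.4 to 66.2). RSP_1944, annotated as a uroporphyrinogen-III methyltransferase, followed at 32.5 (interval 25.0 to 43.1). RSP_1942, a sulfite or nitrite reductase subunit, had 7019 against 149 reads and a ratio of 25.1 (interval 21.4 to 29.8). RSP_1940 had a ratio of 18.0, and cysH (RSP_1941), the phosphoadenylylsulfate reductase of sulfate assimilation, had a ratio of 15.3 (interval 12.5 to 19.0). The methionine uptake genes metN, metI and metQ had ratios of 20.0, 16.3 and 15.9. The cysteine synthase gene cysK1 (RSP_1109) had 9917 against 383 reads and a ratio of 13.8 (interval 12.5 to 15.3), and cysA (RSP_3696), the ATPase subunit of a sulfate transporter, had a ratio of 14.4 (interval 9.14 to 24.2). These genes are the 15 with the highest lower bounds, and their control reads ranged from 12 to 383.

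The 15 features with the lowest upper bounds were led by fliC (RSP_0069), the flagellar filament protein, with 53 reads in the FLAG library against 380 in the control and a ratio of 0.074 (interval 0.055 to 0.099). The filament cap gene fliD had a ratio of 0.102 (interval 0.044 to 0.211), and flgM, an anti-sigma factor of the flagellar system, had a ratio of 0.141. The light-harvesting gene pucB (RSP_0314) had 9426 against 21960 reads and a ratio of 0.229 (interval 0.223 to 0.235). RSP_0313, a hypothetical protein gene that overlaps its start, had a ratio of 0.270 (interval 0.265 to 0.276). The gene for the transcriptional regulator DksA had a ratio of 0.243 (interval 0.192 to 0.306), and its neighbour RSP_7547 had a ratio of 0.245. RSP_6025 at 0.20 and RSP_6219 at 0.089 lie beside each other on chromosome 1. The small RNA RSspA01, on a plasmid, had a ratio of 0.224 (interval 0.193 to 0.260). RSP_3768, RSP_7575, RSP_7559, RSP_6142 and RSP_6091, all hypothetical proteins, had ratios of 0.124, 0.165, 0.184, 0.264 and 0.089.

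**Figure D2:**
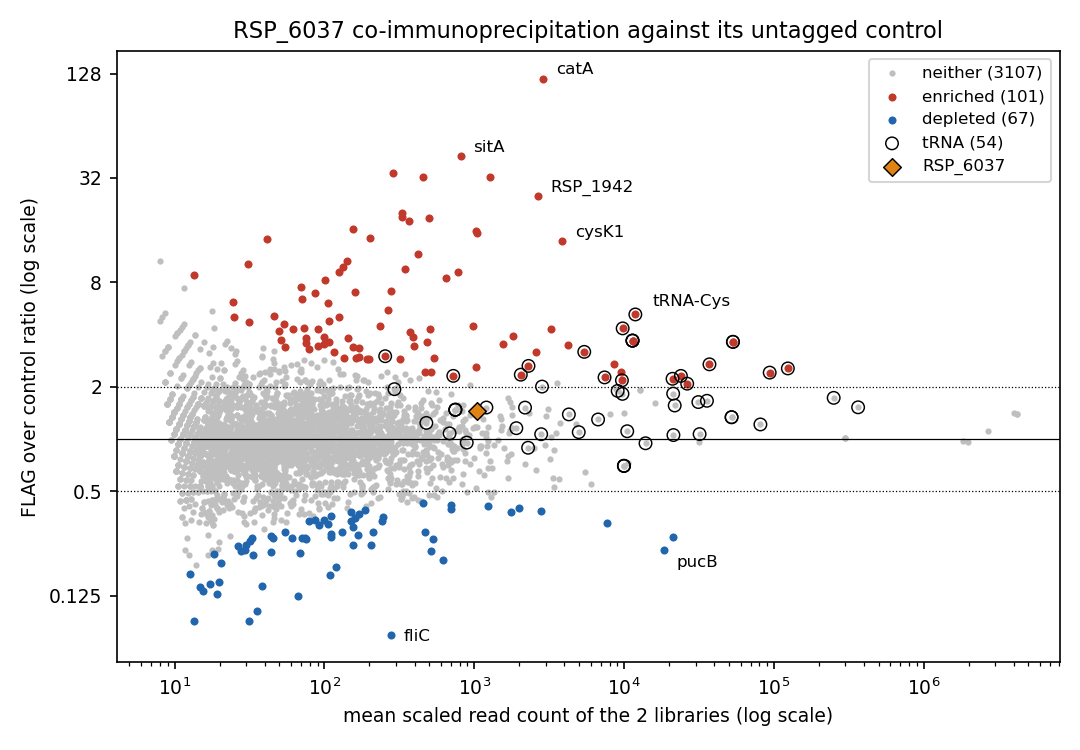
FLAG over control ratio (vertical axis, log scale) against the mean scaled read count of the 2 libraries (horizontal axis, log scale) for the 3275 features with at least 20 reads (red, 101 enriched; blue, 67 depleted; grey, neither; circles, 54 tRNAs; diamond, RSP_6037; dotted lines, ratios of 2 and 0.5). The gene catA stands highest at 120, and fliC stands lowest at 0.074.

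Ribosomal RNA made up most reads of both libraries, with 88.9% of the FLAG library and 90.6% of the control. Transfer RNA made up 8.24% of the FLAG library and 5.89% of the control, small RNAs 0.426% and 0.332%, and coding sequences 2.40% and 3.15%. Each of these shares has an exact binomial interval that reaches at most 0.0152 percentage points to either side. The 5 features with most reads, in each library, were copies of 16S and 23S rRNA. In scaled counts, 23S rRNA had a ratio of 1.40, 16S rRNA 1.02 and 5S rRNA 1.01. As shares of all reads the direction turned for 16S rRNA, with 26.7% of the FLAG library and 33.0% of the control, and for 5S rRNA, with 3.66% and 4.59%, while 23S rRNA stayed higher at 58.6% and 53.0%.

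Of the 54 tRNAs, 20 were enriched and none was depleted, and the interval lay above 1 for 47 and below 1 for 5. Their median log2 ratio was 0.72. The highest ratio was that of tRNA-Cys (RSP_4322) at 5.22 (interval 5.02 to 5.43, 27346 against 2793 reads), and the lowest was that of a tRNA-Met (RSP_4356) at 0.699 (interval 0.679 to 0.719). Copies of tRNA-Ile and of tRNA-Ala in the rRNA operons had identical counts, so reads of near-identical copies appear split between them. With total-count scaling 9 tRNAs were enriched, and the interval lay above 1 for 38 and below 1 for 14.

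Of the 11 known small RNAs with enough reads, 2 were enriched, RSs0680a and RSs0019. RSs0019 had a ratio of 3.88 (interval 2.64 to 5.88) and overlaps the coding sequence RSP_7581, so the counting can split or share their reads. The interval lay above 1 for 10 of the 11, and the median log2 ratio of 1.09 was above that of every random list. RSs2430, known as PcrZ, had a ratio of 1.93 (interval 1.87 to 2.00), RSs1386 a ratio of 2.10 and RSs1740 a ratio of 2.29. RSs2461, known as SorX, was the exception at 0.870 (interval 0.789 to 0.960). RSs2363 overlaps 6S RNA and has the same counts, with a ratio of 1.91. Among all 42 small RNAs, including predicted ones, 4 were enriched and 1 was depleted, and the median log2 ratio was 0.07 (percentile 77.7), which total-count scaling turns negative, with 4 enriched and 4 depleted. The highest was 3'RSP3594, with a ratio of 8.23 (interval 4.97 to 14.6), and the remaining enriched one, named after its value was seen, was sRNA_00028 at 2.69. The small RNA 3'RSP3594 lies directly downstream of the coding sequence RSP_3594 on the same strand. RSP_3594, named after its value was seen, was enriched too, at 14.1 (interval 5.36 to 52.8, 106 against 4 reads).

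Photosynthesis transcripts had low ratios. Of 49 photosynthesis genes, 9 were depleted and none was enriched, the interval lay below 1 for 43, and the median log2 ratio of -0.75 was below that of every random list. Within the list, pucB was lowest and crt (RSP_0913), annotated as an enoyl-CoA hydratase, was highest at 1.38 (interval 0.848 to 2.31). With total-count scaling 23 of the photosynthesis genes were depleted. Motility and chemotaxis transcripts had the lowest median, -1.41 on the log2 scale, also below every random list. Only 27 of the 75 members had enough reads, and of these 9 were depleted and none was enriched. The highest was fliR1 at 2.13, with 16 against 4 reads and an interval of 0.688 to 8.77. ATP synthase genes had a median of -0.49 (percentile 1.03) with no enriched or depleted member of 13. The 9 Calvin cycle genes taken by symbols that start with cbb had a median of -0.50 (percentile 1.94), with cbbF1 depleted at 0.348 (interval 0.272 to 0.444). The symbols missed prkB at 0.226 (interval 0.112 to 0.434) and fbpB at 0.221 (interval 0.128 to 0.370), named after their values were seen, which were depleted too. With 5 genes added by annotated product the median of the 14 was -0.72 (percentile 0.03), with 3 depleted. The 5 nitrogen fixation genes had a median of -0.53 (percentile 6.54), which became 0.09 with no filter on low counts, and no enriched or depleted member. The highest of them, nifR3 at 1.40 (interval 0.862 to 2.34), was taken by its symbol and is annotated as a tRNA-dihydrouridine synthase.

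**Figure D3:**
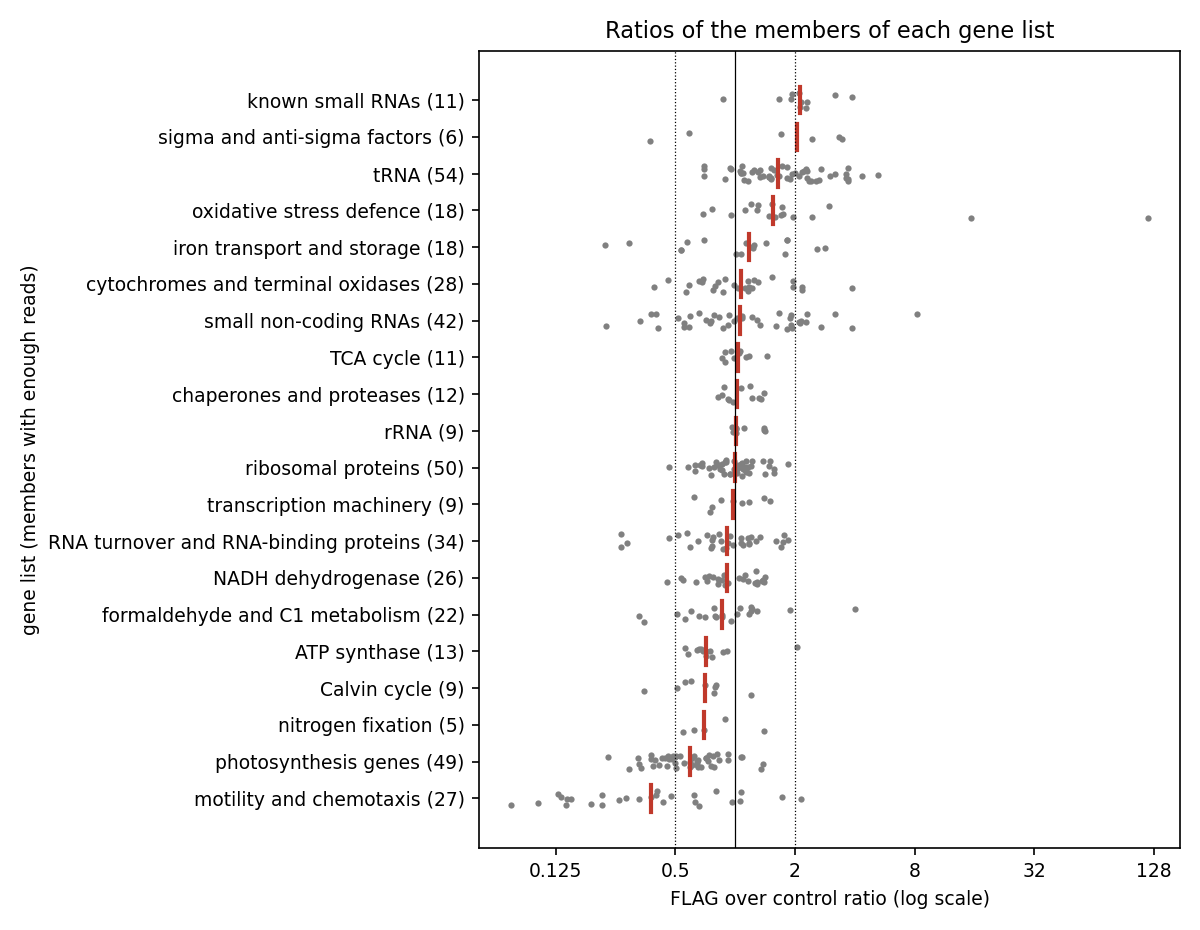
FLAG over control ratio of each member (grey points, horizontal axis, log scale) of the gene lists fixed beforehand with at least 5 members with enough reads (vertical axis, number of members in parentheses), except plasmid-borne genes. Product names were matched without regard to case after the data were examined. Red bars mark the medians of these lists, which run from -1.41 on the log2 scale for motility and chemotaxis to 1.09 for known small RNAs.

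Of 18 genes of oxidative stress defence, 2 were enriched, catA and cysH, the latter listed because its product name contains thioredoxin. The gene catA entered the list after the data were examined, when product names were matched without regard to case. The list's median log2 ratio was 0.64 (percentile 99.97), and grxC, a glutaredoxin, was lowest at 0.685 (interval 0.50 to 0.941). Without cysH the median of the 17 was 0.62 (percentile 99.965), and catA was the only enriched member. Of 6 genes with the sigma and anti-sigma factor symbols rpoE, chrR, rpoH and rpoN, 3 were enriched. They were chrR, the anti-sigma factor of RpoE, at 3.45 (interval 2.34 to 5.25), and, named after their values were seen, rpoH2 at 3.33 and rpoH1 at 2.45. In the same list rpoN2 had a ratio of 0.370 (interval 0.232 to 0.585), and the list median was 1.03, with a wide 95% interval of -1.43 to 1.79 (percentile 99.8). None of the 3 stayed enriched with total-count scaling, where rpoN2 was depleted. These symbols leave out flgM, depleted as given above, and rpoE1, which had a ratio of 2.34 (interval 1.80 to 3.08), was not enriched and is named after its value was seen. With 12 genes added by annotated product, after the values were seen, the median of the 18 was 0.11 (interval -0.78 to 1.18, percentile 80.3), with 3 enriched and 1 depleted.

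Ribosomal protein genes had a median log2 ratio of 0.00 (percentile 47.4) and no enriched or depleted member of 50. The same held for chaperones and proteases with a median of 0.03 (percentile 55.7), the TCA cycle with 0.04 (percentile 57.7), NADH dehydrogenase with -0.14 (percentile 13.8) and the transcription machinery with -0.04 (percentile 39.8). Of the 26 NADH dehydrogenase genes, the interval lay above 1 for 7 and below 1 for 8. All listed genes from RSP_0100 to RSP_0112 had ratios below 1, with nuoA1 lowest at 0.451. Most of those from RSP_2512 to RSP_2530 had ratios above 1, with nuoL highest at 1.40. Among 28 cytochrome and oxidase genes taken by symbol, coxI was enriched at 3.87 (interval 3.19 to 4.74) and ccoQ depleted at 0.388 (interval 0.311 to 0.485), with a median of 0.10 (percentile 76.5). The symbols missed 4 enriched or depleted cytochrome genes, named after their values were seen. Of these, CycF at 4.35 (interval 2.72 to 7.30) and RSP_2395, for a cytochrome c peroxidase, at 2.42 (interval 2.34 to 2.51) were enriched, and RSP_0775 at 0.271 and dorC at 0.218 were depleted. Taken by annotated product, after the values were seen, 45 genes had 3 enriched and 3 depleted members and a median of 0.09 (percentile 81.0). Among 34 genes listed for RNA turnover and RNA binding, of which 7 are annotated as deoxyribonucleases and were taken by that part of their product names, 3 cold-shock protein genes were depleted, with RSP_1952 at 0.267 (interval 0.179 to 0.393) and, named after their values were seen, RSP_3620 at 0.267 and RSP_3621 at 0.284. This list had a median of -0.13 (percentile 15.2), or -0.15 (percentile 15.7) without the 7, and the highest ratio was 1.83 for RSP_1184, a ribonuclease gene. Among 18 iron genes, the ferrous iron transport genes feoA1 at 0.221 and feoA2 at 0.291, the second named after its value was seen, were depleted, and RSP_2913 was highest at 2.84 (interval 2.00 to 4.12). The iron list had a median of 0.23 (percentile 91.8). Its product words leave out the 4 enriched Sit genes and feoB, which was named after its value was seen and had a ratio of 0.562 (interval 0.503 to 0.627). Taken by annotated product, after the values were seen, 27 iron genes had 4 enriched and 2 depleted members and a median of 0.17 (percentile 92.6). With total-count scaling the medians of the ribosomal protein, chaperone, TCA cycle, cytochrome and iron lists turned negative, with 1 depleted NADH dehydrogenase gene and 2 depleted cytochrome or oxidase genes in the list taken by symbol. It also left RSP_2395 not enriched and feoB depleted. The 3 depleted cold-shock genes, feoA1, feoA2 and ccoQ are each at most 300 nt long. Of 211 such short coding sequences, listed after the values were seen, 20 were depleted and 1 was enriched under the main scaling. Over all 3170 coding sequences with enough reads, 66 were depleted and 77 enriched. Whether length accounts for the low ratios of these genes was not tested. Genes of formaldehyde oxidation and C1 metabolism had a median of -0.22 (percentile 11.5), with cbbF1 depleted among 22. Its lowest member, flhA at 0.328 (interval 0.118 to 0.854), and flhA1 at 0.656, named after its value was seen, are annotated as flagellar biosynthesis genes, were taken by symbol and are also in the motility list, and the median was -0.15 (percentile 21.8) without these flagellar genes. The list also holds all 9 cbb genes of the Calvin cycle list, whose own median was -0.50. Outside the cbb and flagellar genes, no member was enriched or depleted. Their ratios ran from 0.853 for RSP_1821, named after its value was seen, to 4.00 for fdsG (interval 1.41 to 15.6, 30 against 4 reads). The median of these remaining genes was not computed, so the negative list median does not describe them. Plasmid-borne genes had a median of -0.22 (below every random list), which became -0.054 with no filter on low counts, with 7 enriched and 2 depleted of 214 features, or 4 and 8 with total-count scaling.

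The authors' deposited table gives a log2 fold change, its standard error and their ratio for each feature. In the authors' deposited table, 30 of 4410 features (0.680%) had a ratio beyond 1.96 in either direction, of which 22 were above and 8 below. The highest, 2.83, belonged to sitA, with a log2 fold change of 5.47. For catA the authors' deposited table gives a log2 fold change of 6.95 with a standard error of 2.53, and for RSP_6037 one of 0.58 with a standard error of 0.67. Of these 30 features of the authors' deposited table, 24 had at least 20 reads, and 21 of them were enriched and 3 depleted by the counting intervals. The deposited log2 fold changes follow from the same counts, so this is no independent check. Conversely, only 21 of the 101 enriched and 3 of the 67 depleted features were beyond 1.96. In the authors' deposited table fliC had -1.95, pucB -0.79, tRNA-Cys (RSP_4322) 0.92 and RSs0680a 1.54.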

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

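The counts of 101 enriched and 67 depleted features stayed within 1.5 times under TMM, upper-quartile and total-count scaling without rRNA and tRNA, and with a minimum of 50 reads or of 1. They also stayed within that range under 4 alternatives chosen after seeing the data, which were the authors' implied size factors, identical counts taken once, rRNA and tRNA left out, and upward rounding. Rounding midway values upward, the rule first used, gave 102 enriched features, 100 of them shared with the 101, and 67 depleted ones, all shared. Total-count scaling lowered every log2 ratio by 0.34 (a shift of -0.34) and gave 63 enriched and 150 depleted features, since rRNA and tRNA enter the total. It moved RSP_6037 to a ratio of 1.14. Limits of 4-fold left 32 enriched and 7 depleted features, and limits of 1.5-fold gave 183 and 185. An assumed coefficient of variation of 0.2 left 58 enriched and 23 depleted features, and one of 0.4 left 29 and 5, so that with no replicates the counts depend on the spread assumed. Total-count scaling also moved the median log2 ratio of rRNA to -0.32, tRNA to 0.38, photosynthesis genes to -1.09, ribosomal proteins to -0.34, RNA turnover to -0.47, chaperones and proteases to -0.31, ATP synthase to -0.83, NADH dehydrogenase to -0.48, the TCA cycle to -0.30 and plasmid-borne genes to -0.56. With no filter on low counts, plasmid-borne genes moved to -0.054. The 5 nitrogen fixation genes are too few for an interval of their median. It was -0.53, and -0.87 under total-count scaling, -0.51 under TMM, -0.57 under total count without rRNA and tRNA, -0.54 under upper quartile, -0.48 under the authors' implied factors and -0.52 with upward rounding. Where the members themselves changed, the median was -0.17 with at least 50 reads, 0.093 with no filter and -0.61 without nifR3. The cause was not tested. Of all 180 values of the lists fixed beforehand 160 stayed within the 95% interval of their median, including those of 8 of the 9 lists taken again by annotated product, an alternative chosen after seeing the data. Of 40 values of the 5 lists put together after seeing the data, 23 stayed within it and 17 did not. The Suf iron-sulfur and Sit lists among these have too few members for an interval, so none of their values counted as staying. The FLAG over control ratio of the share of tRNA reads, 1.40 over all reads, was 1.18 outside rRNA. For coding sequences the ratio of 0.761 became 0.645 outside rRNA and 0.938 outside rRNA and tRNA, and for small RNAs the ratio of 1.28 became 1.09 and 1.58. Of 486 values of named features under other scalings or rounding, 415 stayed inside the counting interval and 70 left it with the same direction or with no direction called. The remaining 1, the 16S rRNA copy RSP_4352, reversed to 0.876 with total-count scaling. Antisense reads as features of their own were not run, because the counts used are of sense reads, and neither were alternatives for the RSP_0557 libraries. No paired analysis was possible because each group has 1 library and no test across replicates was run, and leaving out a replicate does not apply.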

Other observations

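Genes of sulfur, cysteine and methionine metabolism had high ratios beyond those already named. This list, and the other lists in this paragraph, were put together after the enriched genes had been seen, so their counts describe them and are no independent evidence. Of 40 such genes with enough reads, 19 were enriched (15 with total-count scaling) and none was depleted. The sulfate transporter genes cysP, cysT and cysW had ratios of 9.22, 9.78 and 9.21, the sulfate adenylyltransferase gene sopT had a ratio of 4.15 (interval 3.39 to 5.13), and cysS, which charges tRNA-Cys, had a ratio of 2.90 (interval 2.38 to 3.56). Other members were lower, such as metK at 0.568 (interval 0.488 to 0.661) and metZ at 0.690 (interval 0.549 to 0.870). The iron-sulfur cluster genes sufB, sufC and sufD were all enriched, at 3.95, 3.63 and 4.30. Of 10 genes linked to the sigma factor RpoE, 6 were enriched (3 with total-count scaling, which also left cysS not enriched), including RSP_1409 at 7.06 (interval 4.84 to 10.7) and RSP_1091 at 3.46 (interval 2.87 to 4.19), and RSP_1087 was low at 0.457 (interval 0.376 to 0.555).

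All tests below were chosen after the results were seen. The enriched coding transcripts were weighed first. Counting noise is argued against for 46 of the 77 enriched coding sequences, which kept an interval above 2-fold at a level divided by the number of features. The rest did not keep it. Spread between libraries is not covered, and an assumed coefficient of variation of 0.4 left 29 of all 101 enriched features. A single library-wide factor as the whole cause is argued against too, since under any such factor at least 66 of all 3170 coding sequences had an interval beyond 2-fold at that level, although how many lie on the enriched side depends on the factor. Whether these transcripts were bound or were more abundant in the FLAG culture or library batch cannot be told apart, because no library of the lysate was analysed and each group is 1 library. Adjacent genes on the same strand moved together (r = 0.71), as either explanation would predict. These pairs include overlapping genes, whose reads the counting can split or share, which could add to the correlation. For adjacent genes on opposite strands r was 0.088 across 790 pairs, taken without a limit on their distance.

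A library-wide factor does not account for tRNAs lying higher than coding sequences, since the median log2 difference of 0.73 (interval 0.57 to 1.07) is the same under any factor. The extent does depend on the scaling, since total-count scaling lowered the enriched tRNAs from 20 to 9 and raised those with an interval below 1 from 5 to 14. The interval of the median difference takes tRNAs as independent, though some copies had identical counts. Better recovery of short RNAs in general cannot be told apart from a difference specific to tRNA. The 23 measured small RNAs and 5S rRNAs of at most 120 nt had a median log2 ratio of 0.015, but with a wide interval from -0.60 to 1.07. No biological explanation was tested.

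A library-wide scaling factor moves all coding sequences alike, so it does not account for the 76 photosynthesis and motility members lying lower than other coding sequences, by a median log2 difference of -0.99 (interval -1.17 to -0.67). Short coding sequences of at most 300 nt were low in general, with a median log2 ratio of -0.33 for the 203 outside both lists. That does not account for the pattern, since the 68 members above 300 nt had a median of -0.96 (interval -1.13 to -0.67). The intervals of these medians take genes as independent, though adjacent genes on the same strand moved together. A different state of the 2 cultures cannot be told apart from an effect of the tagged protein without a lysate library, and 61 of the 76 members had an interval below 1.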
